A study of Mus musculus with 7 samples.

How the data were processed

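Messenger RNA was measured in 7 libraries of sorted mouse stromal cells, 3 labelled pCAF and 4 labelled NMF. The deposited table held counts per gene symbol, raw and unscaled, for 24421 symbols, of which 7867 were at 0 in every library. Per the labels, libraries were made from the 3' ends of polyadenylated RNA, and the tumor and the fat pad were digested with different collagenase mixtures before sorting. Per the submitters' processing notes, bcl2fastq, STAR 2.4.2a, HTSeq and the mm10 assembly were used, without a statement of their roles. The annotation, strandedness, handling of multi-mapping reads, use of molecular identifiers and any filter were not given in the sources used here. No mitochondrially encoded gene was in the table. Samples were grouped by title and source name, so pCAF replicate 3 was kept in pCAF although its selection field read PDPN negative.

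Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups as design, which left 10535, and libraries were scaled with TMM factors. CPM values were computed here from these effective library sizes and are given as mean ± SD (n = 3 pCAF, n = 4 NMF); principal components and correlations used log2 CPM with a prior count of 2. The groups were compared with edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05; fold changes are those fitted by edgeR, pCAF over NMF. For a gene with no count in a group, the fold is a bound against a floor of 3 counts over the group, 0.557 CPM in pCAF and 0.228 CPM in NMF. For a gene with 1 to 3 counts in a group, the ratio is given with an exact 95% counting interval. Intervals and floors cover counting error only. Total counts per library ran from 1885039 to 4990070. Libraries of a group were compared by a chi-square statistic per degree of freedom on their counts.

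Gene lists, 37 in all, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the 34 lists with at least 3 tested members. Of these, 15 lists rose and 9 fell; with a correlation estimated from the data 6 calls held: matrix glycoproteins and proteoglycans, matrix proteases and inhibitors, myofibroblast contractile genes, glycolysis and lactate export, Wnt antagonists and agonists, and blood endothelial markers. The lists of mitochondrially encoded genes, neutrophil markers and erythroid markers had too few tested members. Cfd, Ctgf, Mfap5, Pdgfrb, Vegfa and Wisp1 were among the genes in 2 lists. The samples, the test, the lists, the alternatives and a rule for named genes were set before the data were examined. The rule took the 12 genes with the largest rise and the 12 with the largest fall among changed genes with a mean of at least 50 CPM and no overlap between the groups, up to 4 members of each list by adjusted p with up to 2 members that went the other way or did not pass, and 16 fixed genes: Runx1, Runx2, Runx3, Cbfb, the sort markers, fibroblast genes and DNA methyltransferases. Fabp4, Il11, Lif, Mmp13, Pecam1, Slc2a1 and Timp1, and a few further list members, were named outside this rule, chosen after their values were seen. Some genes that the rule names are not reported here, and these were also left out of the comparison of single libraries within NMF; they stayed in the fits and in the counts over lists. Gene positions were taken from GENCODE M21 for mm10, to which 23976 symbols were matched. The last 300.0 bp of each gene's transcripts were compared with all others using blastn 2.17.0, counting matches of at least 80 bp at 95% identity or more; 1977 genes had such a copy. Overlaps of the last 1000.0 bp with exons of other genes were listed as well. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

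The alternatives were other scalings (DESeq2 size factors, library totals, upper quartile), other tests (DESeq2 1.42.0, limma-voom, glmTreat), other filters, libraries thinned to the smallest total, the replicate number as a block, each library left out in turn, and fry and an estimated correlation for the lists. Fits without pCAF replicate 1 and NMF replicate 4 together, or with a term for both, were added after the data were seen. Replicate numbers were not used to pair the groups: after removal of group means, the correlations of pCAF and NMF libraries with the same number were -0.09, 0.08 and -0.01. In the replicate block NMF replicate 4, whose number no pCAF library shares, has a term of its own. That fit thus leaves it out of the group comparison and keeps fewer degrees of freedom, which alone can lose calls. The methods were tested on simulated counts for 10535 genes, with 2-fold, 4-fold and 8-fold changes planted in 67, 67 and 66 of them. EdgeR recovered 1.49% of 2-fold, 67.2% of 4-fold and 84.8% of 8-fold changes, and 5 of its 107 calls were of unchanged genes. In the data 28.4% of genes changed, a far larger share, so these rates need not carry over. On the same counts DESeq2 recovered 5.97%, 76.1% and 87.9%, with 27 of 140 calls unchanged, and limma-voom 1.49%, 53.7% and 78.8%, with 3 of 92. All 5 shifted lists were recovered and no other list was called. These were random lists of genes simulated independently, so list calls among correlated genes were not tested this way.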

Results

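The series measured messenger RNA in stromal cells sorted from BALB/c mice, with libraries that read only the 3' ends of polyadenylated transcripts. One group, pCAF, held 3 libraries of cancer-associated fibroblasts, the fibroblasts of tumor tissue. The tumors grew after 100000 4T1-luc cells, a luciferase-carrying mouse mammary carcinoma line, had been injected into a mammary fat pad. They were harvested at a size of 1 cm. The sort removed cells with Ter119, CD45 or EpCAM and kept cells with podoplanin (PDPN), a surface glycoprotein of fibroblasts and lymphatic endothelium. The other group, NMF, held 4 libraries of cells from the normal mammary fat pad, sorted with the same 3 negative markers and without selection on PDPN. The labels gave 8 weeks as the age of the pCAF mice and 12 weeks as that of the NMF mice, while the design text called the groups age matched. For pCAF replicate 3 the selection field read PDPN negative, although its title and source placed it among the PDPN positive cells. Its Pdpn count was 692, between 498 in replicate 2 and 1779 in replicate 1. Total counts were 2184389, 1885039 and 1900554 in pCAF replicates 1 to 3, and 2393024, 2223198, 2714492 and 4990070 in NMF replicates 1 to 4. The labels called the replicates biological without naming the animals behind them, so p-values measure the spread between these libraries.

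Libraries of the same group resembled each other more than libraries of different groups. Across genes, Pearson correlations of log2 CPM ran from 0.83 to 0.974 within pCAF, from 0.892 to 0.965 within NMF and from 0.621 to 0.735 between the groups. pCAF replicate 1 and NMF replicate 4 stood apart from their groups. pCAF replicate 1 had counts for 11090 genes, against 13222 to 14353 in the other 6 libraries, and 165 genes were at 0 in it alone while each of the others held at least 10 counts. The chi-square statistic per degree of freedom was 3.49 between pCAF replicates 2 and 3, more than sampling noise, and 44.3 and 46.8 between each of them and replicate 1. It ran from 7.05 to 11.1 among NMF replicates 1 to 3 and from 38.8 to 43.4 between these and replicate 4.

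**Figure D1:**
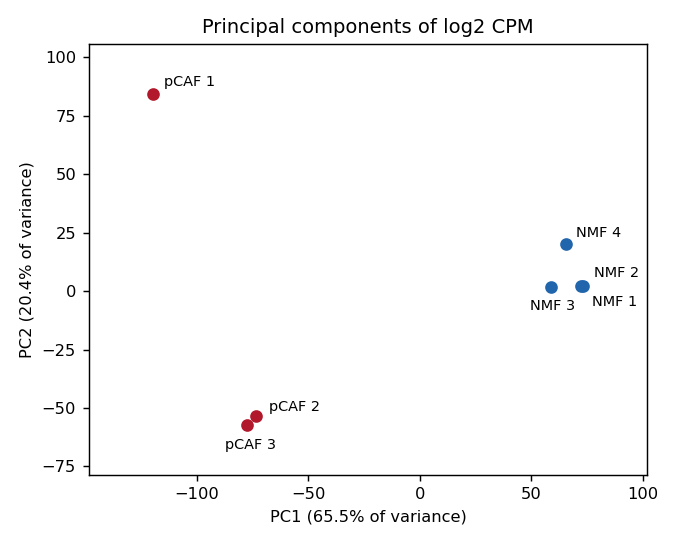
Principal components of log2 CPM over the tested genes, with 1 point per library (red, pCAF; blue, NMF). The horizontal axis, component 1 with 65.5% of the variance, parts the groups, and the vertical axis, component 2 with 20.4%, parts pCAF replicate 1 from pCAF replicates 2 and 3.

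The title of the series names RUNX1, a transcription factor that binds DNA with its partner CBFB, as raised in the stroma of breast tumors, so the first question was how its transcript differed between the groups. Runx1 (mm10 chromosome 16, 92601466 to 92826149, minus strand) was 48.3-fold higher in pCAF, at 155 ± 90.1 CPM (SD, n = 3) against 3.11 ± 1.65 CPM (SD, n = 4) in NMF. Its counts were 92, 363 and 378 in pCAF and 11, 8, 2 and 22 in NMF, and every pCAF library lay above every NMF library. The log2 fold change was 5.59 (SE 0.61), with an adjusted p of 1.76e-04 in edgeR's quasi-likelihood test. Runx2, a regulator of bone formation, was 3.99-fold higher (44.99 ± 16.2 against 11.3 ± 1.45 CPM, adjusted p = 0.00212), and Cbfb was 3.97-fold higher (115 ± 18.3 against 29.1 ± 8.99 CPM, adjusted p = 9.74e-04). Cbfa2t3, a transcriptional corepressor, fell in pCAF, from 16.996 ± 4.33 to 0.742 ± 0.846 CPM (adjusted p = 0.00176; 21.6-fold). Without pCAF replicate 3, where 1 pCAF count was left, NMF held 61.2 times the pCAF level (95% counting interval 10.9 to 2429). Runx3 held 0 to 4 counts per library and was not tested. Of the 5 tested members of the RUNX family and partners list, 3 rose and 1 fell, with the same numbers adjusted over the list alone. The list as a set rose (camera, adjusted p = 0.0441, adjusted p = 0.241 with an estimated correlation). That call was lost without pCAF replicate 2 (adjusted p = 0.0652), without pCAF replicate 3 (0.0651), without NMF replicate 3 (0.0536) and without NMF replicate 4 (0.0925). It was also lost with a mean of at least 10 CPM (0.0711) and with the replicate block (0.0814). The series title also names DNA methylation. Dnmt1, the maintenance DNA methyltransferase, was at 16.01 ± 11.5 CPM in pCAF and 24.04 ± 5.64 in NMF (adjusted p = 0.486). The de novo enzymes Dnmt3a (9.85 ± 6.14 against 22.003 ± 10.1 CPM, adjusted p = 0.181) and Dnmt3b (3.53 ± 1.94 against 9.79 ± 1.73 CPM, adjusted p = 0.0728) did not pass either. Without both libraries that stood apart, a choice made after the data were seen, Dnmt3a and Dnmt3b were lower in pCAF (adjusted p = 0.00938 and 0.0242). Of 16 tested members of the DNA methylation machinery list, Ahcy alone passed (adjusted p = 0.0310; lost without pCAF replicate 2, 0.127, or 3, 0.0769, and without NMF replicate 1, 0.0651, or 2, 0.0789). For Ahcy it was also lost with library totals (0.0587), the replicate block (0.122) and thinned libraries (0.0675). None passed adjusted over the list alone, and the set did not pass (adjusted p = 0.942; median log2 fold change 0.02, mean and test direction negative, -0.07; the direction turned without pCAF replicate 1, 0.995, and without NMF replicate 3, 0.914).

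**Figure D2:**
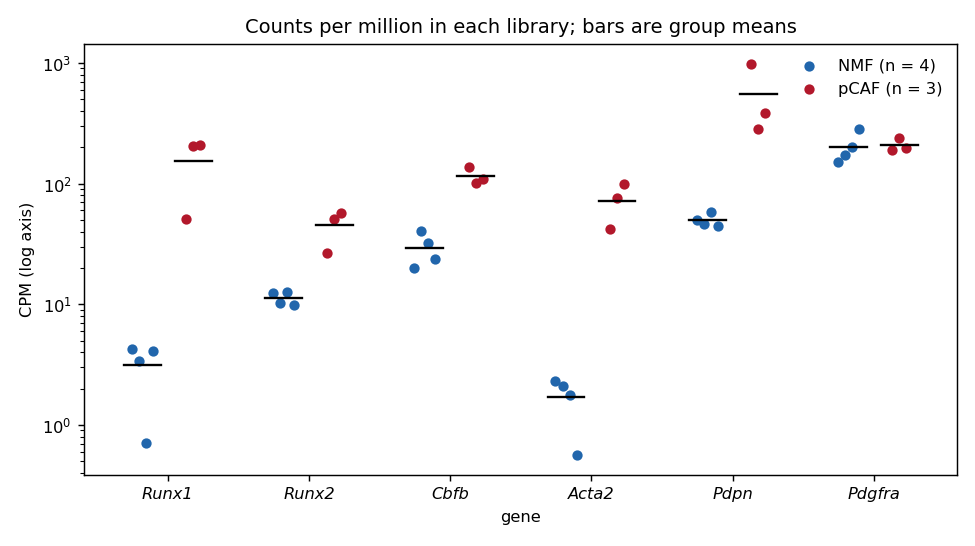
CPM on a log axis for 6 genes, with 1 point per library (blue, the 4 NMF libraries; red, the 3 pCAF libraries) and a bar at each group mean. Runx1, Runx2, Cbfb, Acta2 and Pdpn were higher in every pCAF library than in every NMF library, while the Pdgfra values of the groups overlapped.

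Across the transcriptome, tumor fibroblasts and fat pad cells differed in 28.4% of the genes tested. Of 10535 genes, 1503 were higher and 1491 lower in pCAF at an adjusted p under 0.05, and 1372 and 1400 of these differed at least 2-fold. An unadjusted p under 0.05 was found for 4221 genes. The values of the groups did not overlap in 4253 of the 10535 genes (40.4%), against 5.71% by chance. With library totals alone as the scaling, 37.1% of the changed genes were higher in pCAF, against 50.2% with TMM factors, and the median log2 fold change of all genes was -0.26 in place of -0.02. Without both libraries that stood apart, 2681 genes were higher and 2819 lower. Among the abundant genes with the largest rise were secreted proteins. Saa3, an acute phase protein, was at 2484 ± 646 CPM in pCAF and 3.08 ± 3.04 in NMF (adjusted p = 3.63e-05), although its 3' end has 12 near-identical copies among annotated transcripts, so its share of reads is uncertain; its fold was 834, and 1522 without NMF replicate 3. Spp1 (osteopontin) was 374-fold higher (3197 ± 1764 against 8.56 ± 8.88 CPM, adjusted p = 8.59e-05; 759.8-fold without NMF replicate 3), and Inhba, the activin A subunit, 164-fold higher (958 ± 443 against 5.45 ± 4.19 CPM, adjusted p = 4.87e-05; 261-fold without NMF replicate 4). Prr9 had 733 counts over the pCAF libraries and none in NMF, at least 597-fold more against a floor of 3 counts over the NMF group (adjusted p = 4.09e-04); the bound was 350.5 without pCAF replicate 3 and 356 without NMF replicate 4. For Reg3g, an antimicrobial lectin, with 3 NMF counts, the NMF level was 0.00160 of the pCAF level (95% counting interval 3.30e-04 to 0.00471). It was 6.59e-04 without NMF replicate 1 (1.67e-05 to 0.00368) and 0.00266 without NMF replicate 4 (5.48e-04 to 0.00781). Rises of 66.6-fold to 206-fold were measured for Ltbp2, Ptprn, Aldh1a2, Tnc, Slpi and Col8a1 (largest adjusted p among them, that of Tnc, 1.80e-04); the 3' end of Slpi overlaps another annotated gene, so its share of reads is uncertain. Without NMF replicate 4 Aldh1a2 was 177-fold higher in place of 102-fold, and for Ltbp2, with 3 NMF counts left, the NMF level was 0.00263 of the pCAF level (95% counting interval 5.41e-04 to 0.00772). Large falls were seen in genes of blood vessels and fat. Cd36, a fatty acid transporter, Timp4, Thrsp and the endothelial factor Sox17 had no count in any pCAF library, so they were at least 629.6, 452, 285 and 208 times lower against a floor of 3 counts over the pCAF group. Without pCAF replicate 1 these bounds were 419, 301, 189.5 and 139, and without pCAF replicate 3 they were 419, 301, 189 and 139. Gpihbp1, which anchors lipoprotein lipase on capillaries, fell from 1703 ± 961 to 1.12 ± 1.13 CPM (adjusted p = 3.91e-05; 1464-fold). Without pCAF replicate 2, with 2 pCAF counts left, NMF held 2662 times the pCAF level of Gpihbp1 (95% counting interval 737 to 21985). Cfd, Tie1, C1qtnf9, Rbp7, 8430408G22Rik and Cd300lg kept 1 or 2 counts in pCAF. For Tie1, an endothelial receptor, NMF held 588 times the pCAF level (95% counting interval 105 to 23228), 391 times without pCAF replicate 1 (70.03 to 15446) and at least 136 times without pCAF replicate 3, where no count was left.

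Most groups of extracellular matrix genes were higher in pCAF. Col1a1, which encodes the main chain of type I collagen, rose from 7186 ± 1726 to 28180.3 ± 7516 CPM, 3.92-fold (log2 fold change 1.97, SE 0.31, adjusted p = 0.00126). Larger rises were seen in Col8a1 (66.6-fold), Col12a1 (25.98-fold), Col5a2 (14.7-fold) and Col11a1 (59.5-fold), with adjusted p from 2.07e-05 to 1.46e-04. Col11a1 held 1 to 7 counts per NMF library and was 134-fold higher without NMF replicate 2. Of 17 tested fibrillar and fibril-associated collagens 13 rose, also adjusted over the list alone, where Col14a1 fell; over all genes Col14a1 stood at 236 ± 68.4 against 424 ± 93.7 CPM (adjusted p = 0.0605) and passed without pCAF replicate 1 (0.0249). Without pCAF replicate 2 or NMF replicate 1, 8 collagens rose. The set passed camera with an adjusted p of 4.77e-10 (adjusted p = 0.0850 with an estimated correlation). Of 25 matrix glycoproteins and proteoglycans 18 rose and Fbln1 fell (19 and 2 adjusted over the list alone). These glycoproteins passed as a set both ways (adjusted p = 8.25e-12, and 0.0445 with an estimated correlation). Tnc (tenascin C) was at 1702 ± 1162 against 19.2 ± 8.83 CPM, Bgn (biglycan) at 12960.2 ± 788 against 1224 ± 519 (adjusted p = 1.11e-04) and Ctgf, a matricellular protein, at 806 ± 86.1 against 49.6 ± 10.2 (adjusted p = 2.69e-05). Fn1, fibronectin, did not pass at 6478 ± 114 against 4854 ± 1548 CPM (adjusted p = 0.339). Enzymes that process and crosslink collagen rose in 10 of 17 cases and Tgm2, whose 3' end overlaps a gene on the other strand, fell (11 and 1 adjusted over the list alone; camera, adjusted p = 4.57e-07, adjusted p = 0.0979 with an estimated correlation). The Tgm2 call was lost without pCAF replicate 2 or 3 (adjusted p = 0.0600 and 0.0656) and without NMF replicate 1, 2 or 3 (0.0974, 0.108 and 0.0501). The rises were led by P4ha3 (30.8-fold) and the lysyl oxidase Lox (18.1-fold, adjusted p = 4.68e-05). Matrix proteases and inhibitors rose in 11 of 22 cases and Timp2 fell, from 4035 ± 238 to 906 ± 238 CPM (adjusted p = 5.00e-04). Adjusted over the list alone the numbers were 13 and 1, and the set passed both ways (adjusted p = 1.15e-08, and 0.0445 with an estimated correlation). In that list Mmp13 had no NMF count and was at least 421-fold higher (253 without NMF replicate 4), Timp1 was 54.99-fold higher (adjusted p = 1.26e-04; 86.4-fold without NMF replicate 3) and Mmp9 41.04-fold higher (adjusted p = 6.09e-05). Basement membrane genes did not pass as a set with camera (adjusted p = 0.169) but were lower with fry (0.0213). Of 15, 5 fell, led by Col18a1 (3.78-fold, adjusted p = 0.00192), as did all 22 blood endothelial markers (median log2 fold change -6.05) against NMF cells not sorted on PDPN, and Col15a1 rose 1.86-fold (adjusted p = 0.0286), with the same numbers adjusted over the list alone. The Col15a1 call was lost without pCAF replicate 2 or 3 (adjusted p = 0.0787 and 0.0903) and without NMF replicate 1 or 2 (0.0760 and 0.0784). Basement membrane genes that fell numbered 2 without pCAF replicate 2, and 3 without pCAF replicate 3 or NMF replicate 1, 2 or 4. Without pCAF replicate 1, 2 matrix glycoproteins fell.

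Contractile and TGF-beta genes rose in the tumor fibroblasts. Acta2, the smooth muscle actin used as a marker of myofibroblasts, was 44.9-fold higher (72.1 ± 28.96 against 1.69 ± 0.786 CPM; log2 fold change 5.49, SE 0.51, adjusted p = 6.95e-05), and Cald1 was 17.5-fold higher (965 ± 191 against 55.005 ± 4.19 CPM, adjusted p = 2.47e-05). Of 15 tested myofibroblast contractile genes 14 rose, and 15 adjusted over the list alone. The contractile set passed both ways (adjusted p = 7.66e-17, and 0.00836 with an estimated correlation). Myh9 alone did not pass over all genes (541 ± 244 against 280.4 ± 104 CPM, adjusted p = 0.108), but did without pCAF replicate 1 (0.0134). Among TGF-beta ligands, receptors and targets 10 of 17 rose and the coreceptor Tgfbr3 fell 2.54-fold (11 and 2 adjusted over the list alone, and 2 fell without pCAF replicate 1). Ltbp2, Inhba and Tgfb3 (3.56-fold) were among those that rose. The TGF-beta set had an adjusted p of 9.32e-08 (adjusted p = 0.0896 with an estimated correlation). Of the other fibroblast genes, Pdpn, on which only pCAF had been selected, was 11.1-fold higher (550.2 ± 381 against 49.5 ± 6.36 CPM, adjusted p = 3.09e-04; 6.71-fold without pCAF replicate 1) and S100a4 3.71-fold higher (350.4 ± 49.1 against 94.5 ± 27.5 CPM, adjusted p = 0.00102), though the latter's 3' end overlaps another annotated gene and its share of reads is uncertain. Pdgfra was at 208 ± 27.2 against 201 ± 58.8 CPM (log2 fold change 0.05, SE 0.28, adjusted p = 0.916). Fap, a protease of activated fibroblasts, was at 126 ± 15.4 against 68.4 ± 32.4 CPM and did not pass (adjusted p = 0.0787), but passed without NMF replicate 4 (0.00561) and with the replicate block (0.0242). Pdgfrb, at 304 ± 124 against 145 ± 44.5 CPM, missed the threshold (adjusted p = 0.05002) and passed without pCAF replicate 1 (0.00504). Pdgfrb also passed with DESeq2 size factors (0.0496), DESeq2's test (0.0294), no filter (0.0479) and thinned libraries (0.0456).

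Cytokine genes were higher in pCAF, while interferon and antigen presentation genes did not pass as sets with camera. Cxcl14 rose 21.6-fold, from 109 ± 10.9 to 2356 ± 958 CPM (adjusted p = 3.44e-05), and Ptgs2, the inducible cyclooxygenase, 12.9-fold (adjusted p = 3.28e-04). Cxcl5 was 222-fold higher (adjusted p = 1.79e-04; 143-fold without NMF replicate 4, and at least 294-fold without NMF replicate 2, the only NMF library with a count), and the interleukin 6 family members Lif and Il11 rose 15.98-fold and 20.9-fold. Of 20 tested inflammatory cytokines and chemokines 12 rose and none fell (13 and 0 adjusted over the list alone; camera, adjusted p = 4.12e-07, adjusted p = 0.0956 with an estimated correlation). Without NMF replicate 4, 1 gene of this list fell. These genes had a median log2 deviation of -1.56 in NMF replicate 4 from NMF replicates 1 to 3. Interferon response genes (22 tested, 1 up, 3 down, the same adjusted over the list alone) had a set adjusted p of 0.942. Ifi35 fell 3.85-fold and Iigp1 rose 4.42-fold. Without pCAF replicate 1, 2 interferon genes rose and 5 fell, and 5 class I genes fell. MHC class I presentation genes (11 tested, 1 up, 3 down, the same adjusted over the list alone) had a set adjusted p of 0.244, with B2m 2.74-fold higher and Tapbp 2.57-fold lower. Without both libraries that stood apart the class I set was lower (adjusted p = 0.0425), as it was with fry (0.0184). None of 6 MHC class II genes passed, over all genes or adjusted over the list alone (set, adjusted p = 0.493), and 1 was lower without NMF replicate 4. Of 10 complement genes 3 rose and 2 fell, the same adjusted over the list alone, with Cfb, whose 3' end overlaps another gene and is uncertain, 4.58-fold higher (2.30-fold without pCAF replicate 1) and C1ra 2.66-fold lower. The complement set did not pass (adjusted p = 0.781), its median log2 fold change being 0.07 while its mean, -0.54, and the test's direction were negative. That direction turned without pCAF replicate 2 (0.977) or 3 (0.784) and without NMF replicate 4 (0.941).

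Cell cycle, glycolysis and hypoxia genes were higher in pCAF. Mki67, a marker of cycling cells, was at 52.4 ± 5.68 against 1.87 ± 1.35 CPM, 29.4-fold higher (adjusted p = 1.13e-04), and Birc5 was 12.998-fold higher (22.2-fold without NMF replicate 3). Of 23 tested cell cycle genes 16 rose and none fell (18 and 0 adjusted over the list alone; camera, adjusted p = 3.13e-08, adjusted p = 0.241 with an estimated correlation). Slc16a3, a lactate exporter, rose 60.8-fold, from 4.55 ± 2.003 to 269.7 ± 31.4 CPM (adjusted p = 2.69e-05), the glucose transporter Slc2a1 rose 9.35-fold (adjusted p = 0.00117) and Pkm 4.38-fold (adjusted p = 1.96e-04). In the glycolysis and lactate export list 8 of 12 rose and none fell (8 and 1 adjusted over the list alone, and 1 fell without pCAF replicate 1). Glycolysis passed as a set both ways (adjusted p = 2.13e-05, and 0.0445 with an estimated correlation). Gapdh, whose 3' end has 124 near-identical copies, held 0 to 25 counts in 6 libraries and 1540 in NMF replicate 4, so its level is uncertain. Of 14 hypoxia response genes 9 rose and none fell (11 and 0 adjusted over the list alone; camera, adjusted p = 6.44e-06, adjusted p = 0.146 with an estimated correlation). Among them were Car9 (54.7-fold; without NMF replicate 4, with 3 NMF counts left, NMF held 0.00926 of the pCAF level, 95% counting interval 0.00189 to 0.0274), Egln3 (43.4-fold) and Vegfa (3.86-fold, adjusted p = 5.11e-04). Heat shock genes rose in 6 of 14 cases (8 adjusted over the list alone, adjusted p = 0.00321, and adjusted p = 0.110 with an estimated correlation), with Hspd1 3.64-fold higher. Unfolded protein response genes rose in 5 of 16 (7 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.199 with an estimated correlation), with Hsp90b1 2.95-fold higher; none of either list fell. Without pCAF replicate 1, 9 unfolded protein response genes rose and 2 fell, and 3 rose without NMF replicate 1, 2 or 3. Of 25 oxidative phosphorylation genes 4 rose and none fell, the same adjusted over the list alone, and the set did not pass (adjusted p = 0.0612), while it was higher without NMF replicate 2 (0.0466) and with fry (0.00818). The number that rose was 10 without pCAF replicate 1, 2 without pCAF replicate 3 or NMF replicate 1, and 1 without NMF replicate 2.

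Genes of resting fibroblasts and of fat were lower in pCAF, and so were all 22 blood endothelial markers (median log2 fold change -6.05) in a comparison with NMF cells that had not been sorted on PDPN. Gsn (gelsolin) fell 30.6-fold, from 14728 ± 2658 to 482 ± 77.3 CPM (adjusted p = 2.69e-05), and Dpp4, a marker of progenitor-like fibroblasts, 6.73-fold (adjusted p = 0.00119). Of 22 resting fibroblast genes 10 fell and none rose, Pdgfrb passing adjusted over the list alone (10 and 1; camera, adjusted p = 1.13e-04, adjusted p = 0.126 with an estimated correlation). Resting fibroblast genes that fell numbered 5 without pCAF replicate 2, and 6 without pCAF replicate 3 or NMF replicate 1, 2 or 3. They numbered 8 without NMF replicate 4 and 15 without pCAF replicate 1. Without pCAF replicate 1, 1 resting fibroblast gene and 2 fat genes rose. Pparg, the adipogenic transcription factor, was at 2.24 ± 1.69 against 118 ± 45.7 CPM (adjusted p = 1.12e-04; 51.5-fold lower, and 82.03-fold without pCAF replicate 2) and Fabp4, a fatty acid binding protein of fat and capillaries, at 34.4 ± 29.4 against 9261 ± 6086 (adjusted p = 0.00118). In the adipogenic and adipocyte list 14 of 18 fell and none rose (16 and 0 adjusted over the list alone; camera, adjusted p = 1.18e-10, adjusted p = 0.0803 with an estimated correlation). Plin1 and Lep of that list were not tested, with 0 to 5 counts per NMF library and none in pCAF. Whether the fall of this list came from fat cells or from capillaries was not tested. Of 9 tested steroid and growth hormone receptors 5 fell (6 adjusted over the list alone, and 3 without pCAF replicate 2 or NMF replicate 3 or 4), among them the glucocorticoid receptor Nr3c1 (4.81-fold, adjusted p = 5.44e-04), and the estrogen receptor Esr1 rose 2.53-fold (adjusted p = 0.0147; 0.0518 without NMF replicate 1). That set had an adjusted p of 0.0288 (adjusted p = 0.240 with an estimated correlation), which was lost without pCAF replicate 2 (0.0646) and without NMF replicate 4 (0.0744). It was also lost with a mean of at least 10 CPM (0.0744) and with the replicate block (0.0814). Wnt antagonists and agonists rose in 8 of 15 cases and Sfrp5 fell (9 and 1 adjusted over the list alone, and 2 fell without pCAF replicate 1), with Frzb 76.1-fold and Sfrp1 5.98-fold higher. The Wnt set passed both ways (adjusted p = 7.16e-05, and 0.0445 with an estimated correlation). Of 17 growth factors 7 rose, such as Pgf (5.34-fold, adjusted p = 4.53e-04), and 4 fell, such as Areg (14.2-fold, adjusted p = 0.00945; 9.47-fold without pCAF replicate 1 and 31.99-fold without pCAF replicate 2), or 8 and 4 adjusted over the list alone. Growth factors that fell numbered 2 without pCAF replicate 2 or 3 or NMF replicate 1 or 3. The growth factor set had an adjusted p of 0.0454 (adjusted p = 0.200 with an estimated correlation), lost without pCAF replicate 1, 2 or 3 (0.0723, 0.0859 and 0.0564) and without NMF replicate 1 or 3 (0.0529 and 0.0643). It was also lost with library totals (0.0515) and with a mean of at least 10 CPM (0.0711).

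**Figure D3:**
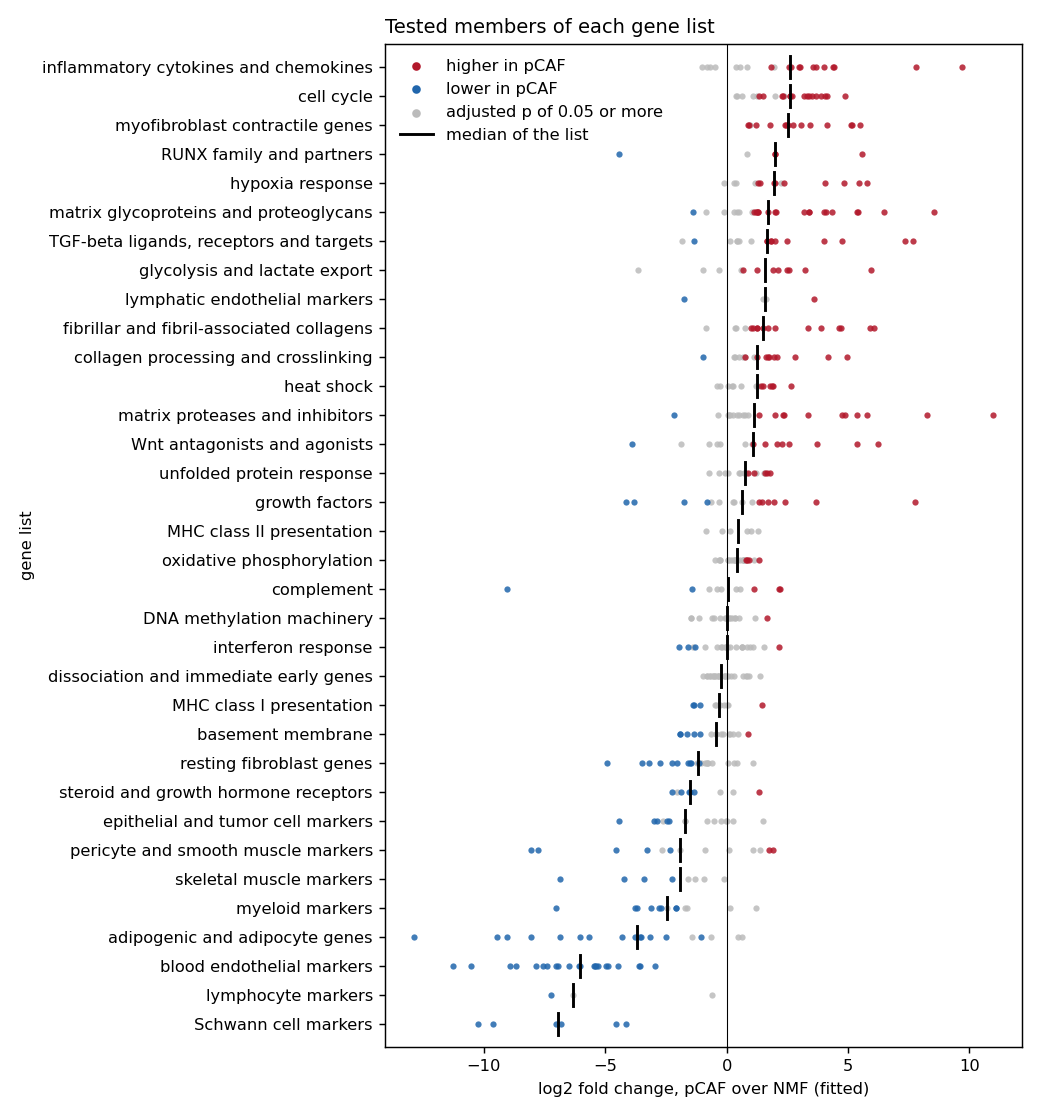
Fitted log2 fold changes (pCAF over NMF, horizontal axis) of the tested members of 34 gene lists (vertical axis), with 1 point per gene and a black line at the median of each list. Red and blue points passed the edgeR threshold and grey points did not; all 22 blood endothelial markers lie to the left of 0, and 14 of 15 contractile genes are red.

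Markers of blood vessels, nerve sheath and several other cell types were lower in pCAF, the group that had been selected on PDPN. All 22 blood endothelial markers fell, also adjusted over the list alone, with a median log2 fold change of -6.05. Pecam1 (CD31) was at 1.49 ± 1.29 against 350.3 ± 72.9 CPM (adjusted p = 3.44e-05) and Aqp1, a water channel, at 24.9 ± 4.03 against 1619 ± 604 (adjusted p = 3.29e-05). The set passed both ways (adjusted p = 3.40e-40, and 0.0445 with an estimated correlation). All 6 tested Schwann cell markers fell, also adjusted over the list alone (camera, adjusted p = 4.80e-07, adjusted p = 0.126 with an estimated correlation). Their median log2 fold change was -6.93, or -5.31 with genes absent from pCAF set at their bound, and the fitted median was -8.16 without pCAF replicate 2. Mbp was 23.5-fold lower (adjusted p = 1.69e-04). Of 13 pericyte and smooth muscle markers 5 fell and 2 rose (7 and 4 adjusted over the list alone): Notch3 fell 5.01-fold and Des rose 3.30-fold, though its 3' end overlaps a gene on the other strand. The pericyte set had an adjusted p of 0.0269 (adjusted p = 0.200 with an estimated correlation), lost without pCAF replicate 1 (0.0560) or 2 (0.0698). That call was also lost with a mean of at least 10 CPM (0.0792), with the replicate block (0.0686) and without both libraries that stood apart (0.115). Of 13 myeloid markers 8 fell (10 adjusted over the list alone, adjusted p = 0.0157, and adjusted p = 0.527 with an estimated correlation; 0.0517 without pCAF replicate 3). The myeloid call was also lost with a mean of at least 10 CPM (0.0904) and with fry (0.0736). Ptprc, which encodes CD45, had no pCAF count, at least 11.3-fold lower (adjusted p = 0.0168, but 0.0612 with limma-voom); the bound was 7.55 without pCAF replicate 1 and 7.55 without pCAF replicate 3. Myeloid markers that fell numbered 5 without pCAF replicate 2 or NMF replicate 2, 4 without NMF replicate 3, and 3 without pCAF replicate 3 or NMF replicate 1. They numbered 11 without NMF replicate 4. Epithelial and tumor cell markers fell in 5 of 15 cases, the same adjusted over the list alone, in 3 without pCAF replicate 2 and in 2 without NMF replicate 1. Without NMF replicate 4 they fell in 7. Krt19 was 5.51-fold lower (adjusted p = 4.53e-04). Epcam was at 2.05 ± 1.79 against 15.3 ± 8.54 CPM (adjusted p = 0.0275; lost without pCAF replicate 2, 0.0569, and without NMF replicate 1 or 2, 0.0874 and 0.0778). Its fold was 7.26, and 4.84 without pCAF replicate 1. The Epcam call was also lost with limma-voom (0.0694) and with the replicate block (0.0812). Their set had an adjusted p of 0.0441 (adjusted p = 0.563 with an estimated correlation), lost without pCAF replicate 1 or 2 (0.127 and 0.0634) and without NMF replicate 1 or 2 (0.0827 and 0.0885). It was also lost with library totals (0.0723), a mean of at least 10 CPM (0.0792) and fry (0.110). Of 8 skeletal muscle markers 4 fell, the same adjusted over the list alone (adjusted p = 0.0269, and adjusted p = 0.376 with an estimated correlation; lost without pCAF replicate 3, 0.0576, and without NMF replicate 4, 0.0623). Muscle markers that fell numbered 1 without pCAF replicate 3, 2 without NMF replicate 1, 3 or 4, and 5 without pCAF replicate 1. Lymphatic endothelial markers (4 tested, Mmrn1 higher and Flt4 lower, the same adjusted over the list alone) had a set adjusted p of 0.482, and were higher with fry (0.0328). Mmrn1 did not pass with the replicate block (0.0519). Lymphocyte markers (3 tested, Cd79b lower, with 2 lower adjusted over the list alone) had a set adjusted p of 0.242, which was 0.0361 without NMF replicate 4, where 2 were lower. Only 1 neutrophil marker, Ltf, could be tested, and it was lower in pCAF (adjusted p = 0.0198). For Ltf it was 0.0603 without pCAF replicate 3, 0.0597 without NMF replicate 2 and 0.145 with limma-voom. Dissociation and immediate early genes, which cells switch on during tissue digestion, showed no member past the threshold among 24, also adjusted over the list alone. As a set they did not pass (adjusted p = 0.942; median log2 fold change -0.22, mean -0.09, the test's direction being up, and down without pCAF replicate 1, 0.735, or NMF replicate 4, 0.181). Without NMF replicate 4, 5 immediate early genes fell, and without pCAF replicate 1, 2 fell and 1 rose. In NMF replicate 4 their median log2 deviation from NMF replicates 1 to 3 was -1.91. Without both libraries that stood apart the set was lower in pCAF (adjusted p = 0.0368).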

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

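All tests of explanations in this part were chosen only after the result was seen, except the test of fewer RNA molecules. A library of the NMF group was listed when its gap to the nearest of the other 3, divided by the range of all 4, exceeded Dixon's 95% critical value for 4 samples, and chance alone lists about 1 in 20 groups. Of 187 values tested, 21 exceeded it, and 9 of these were in NMF replicate 4. Independent, normally distributed values would give 9.3 by chance. Lists were tested beside their own genes and some genes held few counts, so 9.3 is only a rough guide. The pCAF group, with 3 libraries, was not tested this way.

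In NMF replicate 4 the mean log2 CPM of dissociation and immediate early genes was 6.94 (8.62 to 8.85 in the other 3), that of MHC class II genes 2.73 (5.27 to 5.50), that of lymphocyte markers 0.31 (2.97 to 3.17) and that of oxidative phosphorylation genes 7.18 (7.53 to 7.60). Ier3, an immediate early gene, was at 134 CPM in this library against 835 to 893 in the others. Higher in the same library were Lama2, a laminin chain whose 3' end overlaps a gene on the other strand, at 1146 CPM, Bgn at 2001 CPM, and the endoplasmic reticulum chaperones Hspa5 at 929 CPM and Canx at 67.4 CPM. Several genes that rose in pCAF had a single NMF library above the other 3: Spp1 was at 21.8 CPM in replicate 3 (3.09 to 4.67 elsewhere), Col8a1 at 13.7 CPM and Rrm2, a ribonucleotide reductase subunit, at 13.7 CPM in the same library, and Col11a1 at 2.96 CPM in replicate 2. Mmp10 (0.422 CPM) and Cxcl5 (1.69 CPM) were seen in NMF replicate 2 and Nrg1 (0.386 CPM) in replicate 1. Each had no count in the other 3 NMF libraries, so its gap was the largest possible. For Mmp10 and Nrg1 the value is a single count. In NMF replicate 3, Gsn was at 18672 CPM, above the others, and Cbfa2t3 (10.6 CPM) and Tap2 (111 CPM) lay below them. In NMF replicate 1, Krt19 was at 214 CPM and the mean log2 CPM of contractile genes at 5.91, both above the others.

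pCAF replicate 1 and NMF replicate 4 lay apart from the other libraries of their groups. Reads from near-identical gene copies, counted differently in NMF replicate 4, were argued against only as the source of most of its deviations. Of its genes over 4-fold away 3.76% had such a copy, against 3.89% of the others (odds ratio 0.965, Fisher's exact test, two-sided, p = 1). Different counting of single genes with copies, such as Gapdh, was not excluded. A technical difference shared by both libraries stayed open: of 88 genes over 4-fold away in both, 67.0% deviated the same way, between the bounds of 60% and 80% set for the test. Fewer RNA molecules in pCAF replicate 1 also stayed open. Variation beyond Poisson noise was 4.95 times larger in the lowest than in the highest abundance class. That was just under the bound of 5 for this cause. In NMF replicate 4, which had the most counts, this variation fell more steeply, from 2.13 in the lowest to 0.203 in the highest class. The measure thus does not single out pCAF replicate 1. No biological explanation was tested, and differences between animals or tumors stay open.

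All 24 immediate early genes and 15 of 20 cytokine and chemokine genes were lower in NMF replicate 4 than in NMF replicates 1 to 3. Fewer immune cells in this library stayed open as a source, although the sort removed cells with CD45 and Ptprc, which encodes it, held 5 to 23 counts per NMF library: all 13 myeloid markers were lower, and while the CPM they lost were 1.74% of those lost by the immediate early and chemokine lists, what immune cells express was not measured. A weaker dissociation response is a candidate explanation that stayed open too: the immediate early genes had a median log2 deviation of -1.91, below each of the random lists matched on expression. The chemokine list (-1.56) and the myeloid markers (-1.74) also lay below their random lists, so these values do not separate the explanations. The animal or its fat pad, as a biological difference, was not tested and stays open.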

How the results depend on the processing

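The fits without both libraries that stood apart, and with a term for them, were chosen only after the result was seen. All 2994 changed genes kept their direction under every alternative that tested them (2531 with a mean of at least 10 CPM), and Runx1 passed throughout, with log2 fold changes of 5.29 to 6.23. DESeq2 called 3792 genes and limma-voom 2850, of which 2988 and 2699 were among the 2994. Leaving out 1 library gave 1037 to 1920 genes higher, 1032 to 2122 lower and 19 to 24 changed lists. Genes higher in pCAF numbered 978 with the replicate block and 2681 without both libraries, where 2819 were lower. Tested against a 2-fold change, as glmTreat does by a stricter null, 621 were higher and 730 lower. Changed lists numbered 6 with an estimated correlation. The median correlation between groups, 0.671, was -0.345 over the most variable genes, which are those that part the groups. Of results that did not pass, Pdgfra turned to -0.18 with library totals and, at lowest -0.063, without pCAF replicate 2 or NMF replicate 1 or 2 (leaving out 1 library, up to 0.29), Cd74 to -0.019 without both libraries and Cd3e to 1.06 with limma-voom. The interferon response list turned direction with a mean of at least 10 CPM (adjusted p = 0.984), without pCAF replicate 1 (0.790), without NMF replicate 3 (0.875), without both libraries (0.900) and with fry (0.911), and leaving out 1 library gave 0.732 to 0.941. MHC class II turned without both libraries (0.609), complement there (0.960), without pCAF replicate 2 (0.977) or 3 (0.784) and without NMF replicate 4 (0.941; leaving out 1 library, 0.406 to 0.977), and DNA methylation with a mean of at least 10 CPM (0.984), without pCAF replicate 1 (0.995) and without NMF replicate 3 (0.914; leaving out 1 library, 0.784 to 0.995). Immediate early genes turned with the block (0.141), without pCAF replicate 1 (0.735), without NMF replicate 4 (0.181), without both libraries (0.0368, past the threshold) and with fry (0.951), and leaving out 1 library gave 0.181 to 0.957; the cause was not tested in any of these. Genes with few counts limit the folds, as the floors of 0.557 and 0.228 CPM show.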

Other observations

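The tests in this part were chosen only after the result was seen, except the counts over other splits and the test of the Hox genes; the cartilage and bone, acute phase and Hox lists were themselves chosen after the data were seen. Several genes of cartilage and bone were higher in pCAF. Prg4 (lubricin) was 25.4-fold higher (292 ± 76.996 against 11.5 ± 1.41 CPM, adjusted p = 2.11e-05), the collagen-binding proteoglycan Fmod 13.95-fold (158 ± 35.5 against 10.8 ± 9.76 CPM, adjusted p = 7.37e-04) and Cilp, a protein of the cartilage interlayer, 6.36-fold (adjusted p = 0.00662). Without NMF replicate 4, Fmod was 26.9-fold and Cilp 12.4-fold higher. Of 10 tested genes 8 rose and none fell, of which Spp1, Col11a1 and Runx2 were in the lists set earlier; Sox9 was at 6.32 ± 2.60 against 7.68 ± 3.15 CPM (adjusted p = 0.782). Camera gave p = 5.87e-08, and p = 0.00238 with an estimated correlation, but since the list was put together after its members' values were seen, these are no test of whether such genes rise together.

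Several acute phase and antimicrobial genes were higher in pCAF as well. Serpina3n, a protease inhibitor, was 6.77-fold higher (1145 ± 81.1 against 169 ± 52.98 CPM, adjusted p = 1.93e-04) and Lbp, which binds bacterial lipopolysaccharide, 5.24-fold (1419 ± 1135 against 271 ± 69.4 CPM, adjusted p = 0.00411; 2.83-fold without pCAF replicate 1). Of 10 tested genes 6 rose and Ltf fell (adjusted p = 0.0198; 0.0603 without pCAF replicate 3, 0.0597 without NMF replicate 2 and 0.145 with limma-voom). Camera gave p = 1.88e-07, and p = 0.00284 with an estimated correlation, which for the same reason test nothing here. Of 24 tested Hox genes, which mark position along the body, 11 changed: 3 rose, such as Hoxa11, and 8 fell, such as Hoxd9 (12.6-fold, adjusted p = 0.00341) and Hoxd4 (6.43-fold, adjusted p = 0.00152). Those that rose numbered 5 without pCAF replicate 1 and 1 without NMF replicate 1, 2 or 3, and those that fell numbered 5 without pCAF replicate 3 and 4 without NMF replicate 2. Fat pads from different body positions may be a source of these 11 changes, but other cell types in the sort were not excluded. The Hox genes as a set did not pass (camera, adjusted p = 0.176 over the lists chosen after the data were seen). Camera looks for a shift in a common direction, so with changes both ways its result does not bear on body position.

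All 22 blood endothelial markers were lower in pCAF than in NMF. With an estimated correlation, the marker sets of other cell types that could be tested did not pass. At the preset correlation the Schwann cell, pericyte, myeloid, epithelial and skeletal muscle sets were lower too (camera, adjusted p from 4.80e-07 to 0.0441). All 6 tested Schwann cell markers fell, with a median log2 fold change of -6.93. Of 4 tested lymphatic endothelial markers 1 rose and 1 fell, with a median of 1.58 (camera, adjusted p = 0.482). RNA of tumor epithelial cells in pCAF stayed open: epithelial and tumor cell markers had a median log2 fold change of -1.73 (-2.42 without pCAF replicate 3; set, adjusted p = 0.563 with an estimated correlation), 5 fell and none rose, but NMF expressed them as well, and Krt18 was at 109 ± 61.1 CPM in pCAF against 129 ± 70.6 in NMF. The pCAF sort against EpCAM would remove such cells where they carry it, and Epcam held 0, 5 and 6 counts in pCAF. A lower share of fibroblasts in NMF, as the whole cause of the higher matrix genes, would raise all fibroblast genes by about 1 factor. The median of the collagens exceeded that of the resting fibroblast genes by 2.68 on the log2 scale. The permutation p was 1e-05, the smallest that the permutations can give, with genes treated as independent. This argues against that cause only where other cells of the NMF sort do not express resting fibroblast genes, which was not tested. Cells of other types in the NMF sort, which was not gated on PDPN, are a candidate explanation of the blood endothelial markers, with a median log2 fold change of -6.05. The pCAF sort kept cells with PDPN, so these markers do not measure the vessels of the tumor, and a loss of vessels there was not tested.

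The number of changed genes was compared over all 35 splits of the 7 libraries into 3 and 4. Only 1 split, the real one, gave as many as 2994 genes, and the highest of the others gave 1. All others put libraries of both groups on the same side, which adds the group difference to the spread there. With 35 splits, 1 in 35 is also the smallest share possible, so this comparison alone does not exclude chance. For the lists the real split gave 24, 1 of the 35 as large, and the highest other gave 23. The other 34 splits gave 4 to 23 lists with at most 1 changed gene, so the list count is a weaker measure. The 3 pCAF libraries cannot be shared evenly between sides of 3 and 4, so these splits keep part of the group difference. Whether this alone keeps the list count high was not tested.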
